A study of Rattus norvegicus with 8 samples.

How the data were processed

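The series holds 8 bulk RNA libraries of rat spinal cord, upper lumbar by the series title and upper spinal cord by the sample labels, 4 taken 4 days after T9 hemisection and 4 from rats without spinal cord injury. Per the labels' protocols, cords were frozen in liquid nitrogen, libraries followed CEL-Seq2 and the platform was an Illumina HiSeq1500. Groups were taken from the group label of each sample and replicate numbers from the titles. Whether uninjured rats had sham surgery, what the replicate numbers stand for and whether each library came from its own animal are not given in the sources used here. The p-values then measure only the spread between these libraries, which may be technical.

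The deposited table holds raw UMI counts per Ensembl gene, whole numbers that were not normalized. Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.6.0 and the genome build Rnor_6.0 were used. The annotation release, the UMI length, how UMIs were collapsed, whether strand was used and any read filter are not given in the sources used here. Without stated strand, reads of overlapping or antisense genes cannot be told apart. Columns were matched to samples by the codes that column names and titles share, and 0 columns were left unmatched. Every entry of the table names a gene. Of the 32883 identifiers, 0 matched an entry of the RefSeq gene table of assembly GRCr8, so no gene is named. For the same reason the 37 gene lists fixed beforehand, covering cell types, immune and injury responses and others, were not analysed here, nor was the share of mitochondrially encoded genes.

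Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, at a minimum count of 10 and a minimum total of 15, which left 3073 genes with 89.0% of all counts. Libraries were scaled by TMM, and glmQLFit and glmQLFTest tested injured against uninjured over all 8 libraries, with Benjamini-Hochberg adjusted p below 0.05. Standard errors are the fitted log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled totals of the tested genes, and principal components use log2 CPM with a prior count of 2. Libraries of a group differed by more than counting noise in all 12 comparisons within groups (chi-square per degree of freedom from 2.55 to 7.27), so none was left out as a duplicate. Separately made libraries of the same animal could also exceed counting noise, so the test does not show that the animals were separate.

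Injured and uninjured libraries share the numbers 1 to 4. They were taken as paired if each same-number correlation of deviations from the group mean was over 0.1. Over the 3073 genes, which are not independent replicates, these correlations were 0.389, 0.297, 0.342 and 0.423, and each library correlated best with its own number (other pairs -0.311 to 0.241). The numbers thus come from the titles, while the decision to treat them as pairs comes from the data, since no label calls the libraries paired. Counts of calls with the number as a block stand beside those without it where they differ by over 1.5 times. The adjusted p-values of the single genes are from the fit without the block.

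The test without the block, the alternatives not named below as added and the rule for single genes were fixed before the data were examined. That rule took genes past the threshold with a mean count of at least 10 and no overlap between groups, by size of change, up to 12 per direction. It left 67 higher and 6 lower genes to choose from, of which 2 per direction are printed. The parts of the rule that go by gene symbol could not be applied.

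Library totals ran from 112264 to 320199 UMIs. The median tested gene had a mean count of 22.8, and the median SE was 0.32 in log2 without the block and 0.27 with it. The fits were tested on simulated data for this comparison, 5 sets of counts for the 3073 genes with the real means, library sizes and fitted dispersions and 200 genes changed. The simulated counts held no differences between pairs. Without the block, edgeR found 5.2% of 1.5-fold, 33.2% of 2-fold, 86% of 3-fold and 95.6% of 4-fold changes, so that most simulated 2-fold changes were missed in that fit. With the block and its smaller dispersions it found 26.4%, 66.4%, 96.4% and 99.2%. The false share of calls was 5.17% without and 5.38% with the block, and all 550 and all 721 changed genes called had the right direction. Each simulation used the dispersions of the fit it tested. The false share therefore cannot show whether the smaller dispersions with the block hold in the real data. DESeq2 with the block found 30.8% of 2-fold changes, with 0.741% of calls false, and limma-voom 64% with 5.33% false. Without the block DESeq2 also found 30.8%, with 4.52% false, and limma-voom 29.6% with 3.87% false. These simulations gave DESeq2 only the 3073 genes, so they do not describe its fits to the real counts, run without filterByExpr. Library measures were compared by two-sided exact permutation tests without the pairing and, added after seeing the data, over the 4 pairs (SciPy 1.17.1). Equal depth means random thinning of each library to 112264 UMIs, with the median of 11 draws.

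Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), the earlier quasi-likelihood method of edgeR, other scalings, filters and thresholds, the 10 most abundant genes left out, the replicate block, and each library left out in turn. Thinning for the gene tests, a correction for tag collisions that assumes random 6-base tags, the classes of numbers as a term and all alternatives to the blocked fit were added after seeing the data. On the real counts DESeq2 was run on all 32883 genes without filterByExpr, so it did not test the same genes as edgeR.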

Results

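RNA was measured in the spinal cord of Sprague Dawley rats, an outbred laboratory strain. The series title places the tissue in the upper lumbar cord, while the sample labels call it upper spinal cord, and what the code shared by all sample titles stands for is not given in the sources used here. Cord was taken 4 days after a hemisection, a cut through one side of the cord, at thoracic level 9 (4 libraries), or from rats without spinal cord injury (4 libraries). The comparison asks how the injury affects the transcriptome of cord that was itself left intact, which lies below the level of the cut only if the tissue is lumbar, as the title has it. Libraries were made by CEL-Seq2, which reads the 3' end of each transcript with a random tag, the unique molecular identifier (UMI), so that values are UMI counts per gene. Uninjured libraries 1 to 4 held 221177, 112264, 134499 and 135994 UMIs, and injured libraries 1 to 4 held 272878, 320199, 253670 and 195113. The table listed 32883 Ensembl rat gene identifiers, of which 12612 had a count in at least 1 library. The files do not pair these identifiers with gene names, so changes are described by their number and size, and 2 identifiers are given for each direction.

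After injury, 70 of the 3073 genes tested were higher and 6 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, 4 libraries per group). The genes that rose did so by a median of 3.11-fold, from 1.84-fold to 10.6-fold. Of them, 65 rose by more than 2-fold, 17 by more than 4-fold and 2 by more than 8-fold. The 6 genes that fell had log2 fold changes between -1.22 and -0.87, with a median of -1.07. Together the 70 genes, chosen for their rise, made up 4.41% ± 0.547 (SD, n = 4) of the scaled counts of tested genes in injured cord and 1.46% ± 0.0979 (SD, n = 4) in uninjured cord. In 68 of the 70 and in all 6, every injured library lay on one side of every uninjured library. Such a separation was seen for 9.05% of all tested genes, against 2.86% by chance for 4 libraries against 4. The 70 and the 6 were called from the same libraries, which by itself favours separation. The other 2997 genes did not pass the test. An unadjusted p under 0.05 was found for 441 genes, where chance alone would give about 154, and for 741 with the block described next. Of the 441, 261 were higher and 180 lower. Leaving out 1 library gave between 38 higher genes (without uninjured 1) and 115 (without injured 4), and between 0 lower genes (without injured 1, 139 at an unadjusted p under 0.05) and 15 (without uninjured 4).

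With the number that injured and uninjured libraries share in their titles as a block, 208 genes rose and 140 fell (edgeR adjusted p below 0.05), including all 70 and all 6 of the fit without it. Of these, 126 rose by more than 2-fold and 17 fell by more than 2-fold. The median log2 fold change was 1.12 among the risen and -0.70 among the fallen genes. The change had the same direction in 4 of 4 pairs for 195 of the 208 and for 124 of the 140, as it did for 29.3% of all tested genes and would by chance for 12.5%. The 208 and the 140 were called from the same pairs, which by itself favours such agreement. A block on other pairings of these libraries, counted after seeing the data, gave up to 248 genes, against 348 on the shared numbers. Higher genes made up 92.1% of the calls without the block and 59.8% with the block on the shared numbers. With the block and total counts as the only scaling, 309 genes were higher and 60 lower, a share of 83.7%. DESeq2, run on all 32883 genes without filterByExpr, called 83 higher and 19 lower genes without the block and 80 and 33 with it. Its count of higher genes thus did not grow with the block as that of edgeR did, though the tools did not test the same genes. At equal depth edgeR with the block called 127 and 86. Leaving out 1 pair gave from 95 higher and 47 lower genes (without pair 1) to 318 higher and 202 lower (without pair 4), with 91 lower without pair 2 and 63 without pair 3.

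**Figure D1:**
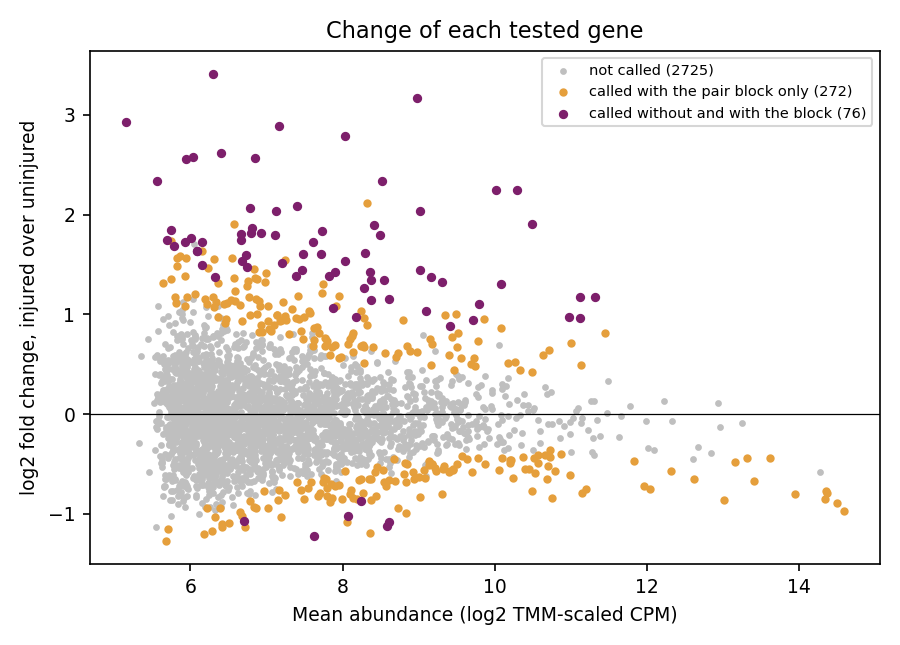
log2 fold change of injured over uninjured cord (fit without the block) against mean abundance (log2 of TMM-scaled CPM) for each tested gene. Of these, 76 genes were called with and without the block, 272 only with it and 2725 in neither, and the largest changes among the called genes are rises.

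The gene with the largest rise was ENSRNOG00000013057, at 144 ± 67.1 CPM in injured and 13.1 ± 4.22 CPM in uninjured cord (SD, n = 4), a log2 fold change of 3.41 (SE 0.48, edgeR adjusted p = 0.000508). It rested on 12 to 72 UMIs per injured library and 1 to 3 per uninjured library. ENSRNOG00000010208 was more abundant, at 909 ± 225 CPM in injured and 102 ± 73.2 CPM in uninjured cord (SD, n = 4), with a log2 fold change of 3.17 (SE 0.35, edgeR adjusted p = 0.000101). Its highest uninjured value, 212 CPM in library 4, lay apart from the 61.8 to 71.6 CPM of the other three. Both genes stayed past the threshold when any 1 library was left out. Among the genes called lower without the block, ENSRNOG00000024506 was at 118 ± 37.9 CPM in injured and 275 ± 87.6 CPM in uninjured cord (SD, n = 4), a log2 fold change of -1.22 (SE 0.30, edgeR adjusted p = 0.0367). ENSRNOG00000025235 was at 243 ± 59.1 CPM in injured and 527 ± 68.1 CPM in uninjured cord (SD, n = 4), a log2 fold change of -1.12 (SE 0.23, edgeR adjusted p = 0.0146). ENSRNOG00000024506 lost its call in 6 of the 8 fits without 1 library (edgeR adjusted p up to 0.132, without injured 1), all but those without uninjured 1 and injured 4, with log2 fold changes of -1.33 to -1.04 in these 6. ENSRNOG00000025235 lost it in 3, without uninjured 2, injured 1 or injured 2 (edgeR adjusted p up to 0.0651), with log2 fold changes of -1.06 to -1.02. The 12 genes with the largest rises under the rule for single genes had log2 fold changes from 2.25 to 3.41.

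**Figure D2:**
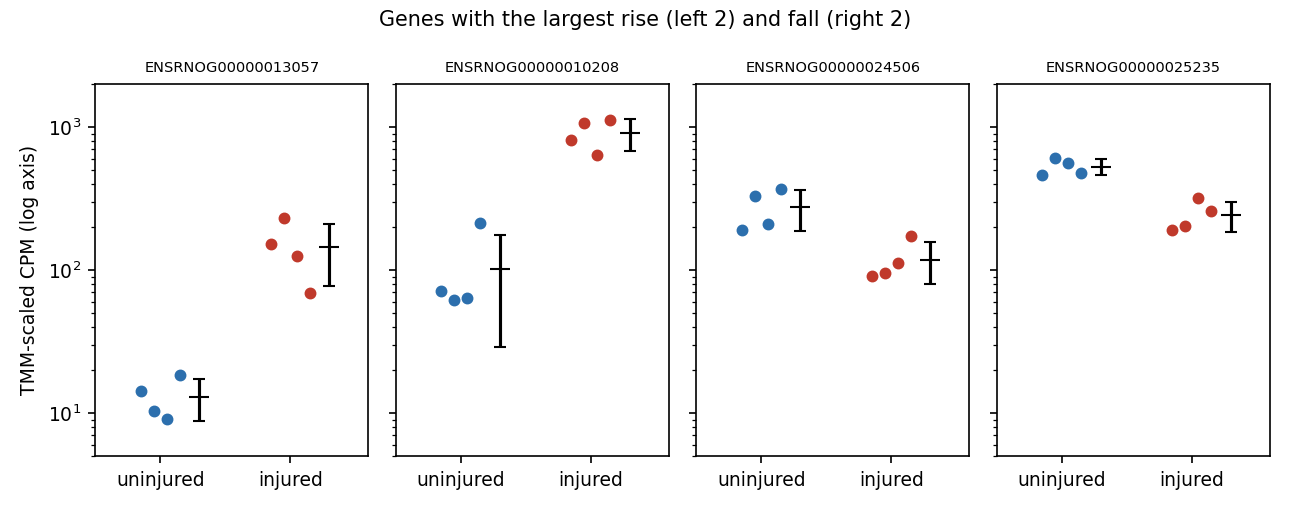
TMM-scaled CPM (log axis) of the 2 genes with the largest rise and the 2 with the largest fall among genes called without the block that had a mean count of at least 10 and no overlap between groups, 1 point per library, with the mean and SD of the 4 libraries of each group in black. ENSRNOG00000010208 lies between 637 and 1116 CPM in injured and between 61.8 and 212 CPM in uninjured libraries.

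Libraries of the same number differed from their group means together. On the first principal component, with 30.2% of the variance, numbers 1 and 2 scored highest within each group, number 4 lowest and number 3 between them, nearer to number 1 than to number 4. The second component, with 26.0%, was higher in the injured than in the uninjured library of each pair. Injury was also tested within numbers 1 and 2 and within numbers 3 and 4, classes chosen after seeing the data. Within numbers 1 and 2, edgeR called 189 genes higher and 61 lower, while DESeq2, run without filterByExpr, called 92 genes in all and limma-voom 191. Within numbers 3 and 4, edgeR called 0 genes, with 188 at an unadjusted p under 0.05, while DESeq2 called 5 and limma-voom 0. All 70 higher and all 6 lower genes had the same direction in both classes, although they were chosen from the same libraries. The interaction of injury and class, the test of the difference itself, called 1 gene (edgeR adjusted p = 0.0351), with 117 genes at an unadjusted p under 0.05 against about 154 by chance. Apart from that gene, chosen after its values were seen, the response was not shown to differ between the classes.

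**Figure D3:**
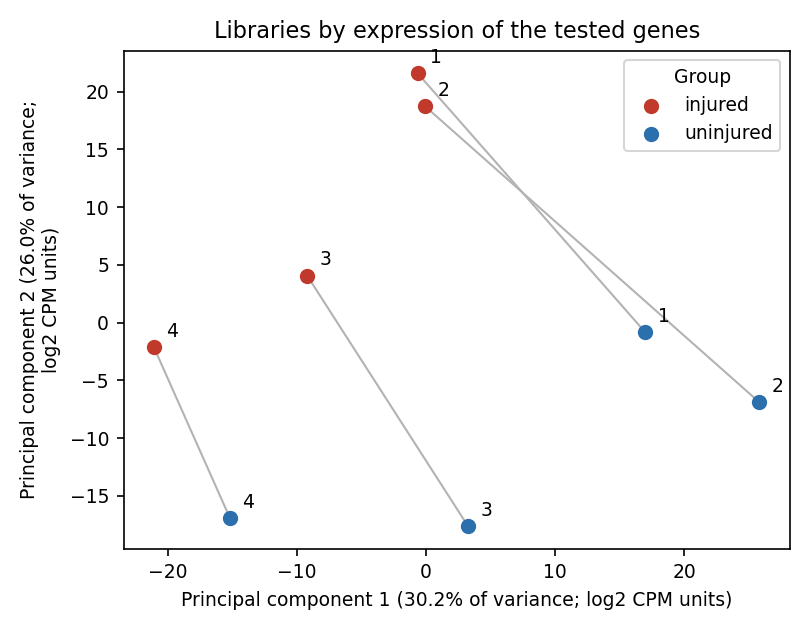
Scores of the 8 libraries on the first and second principal components of log2 CPM over the 3073 tested genes, with the percentage of variance of each, coloured by group, numbered as in the titles and joined by number. In each of the 4 pairs the injured library lies higher on the second component and lower on the first than the uninjured one.

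Injured libraries held 260465 ± 51766 UMIs (SD, n = 4) and uninjured libraries 150984 ± 48037 (SD, n = 4), a difference that did not pass a two-sided exact permutation test (p = 0.0571, where 0.0286 is the smallest possible). At an equal depth of 112264 UMIs, 8080 ± 167 (SD, n = 4) genes were detected in injured and 7694 ± 146 (SD, n = 4) in uninjured libraries, without overlap (two-sided exact permutation p = 0.0286, adjusted over 4 measures 0.0571). The nearest libraries were injured 4 with 7882 and uninjured 1 with 7873 genes. Thinning levels the totals only, so a difference between libraries in the share of abundant genes stays in these numbers. The 10 most abundant genes took 12.5% ± 2.13 (SD, n = 4) of the counts in injured and 18.9% ± 3.91 (SD, n = 4) in uninjured libraries (two-sided exact permutation p = 0.0571). A limit on the counts of abundant genes, considered below, would lower this share in deeper libraries. After adjustment over the 4 measures, none of them, total UMIs and detected genes at full depth included, passed 0.05. Those tests ignored the pairing. In 4 of 4 pairs the injured library had more UMIs, more detected genes at full and at equal depth, and a lower share in the 10 most abundant genes (two-sided exact paired permutation p = 0.125 for each, the smallest that 4 pairs allow). No count in the table exceeded 4047, although library totals differed. The 13 genes with a count above 2048 in any library had a median log2 fold change of -0.67. Without the block edgeR called 0 of them, with 7 at an unadjusted p under 0.05, and with it 9 of them were among the 140 lower genes.

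**Figure D4:**
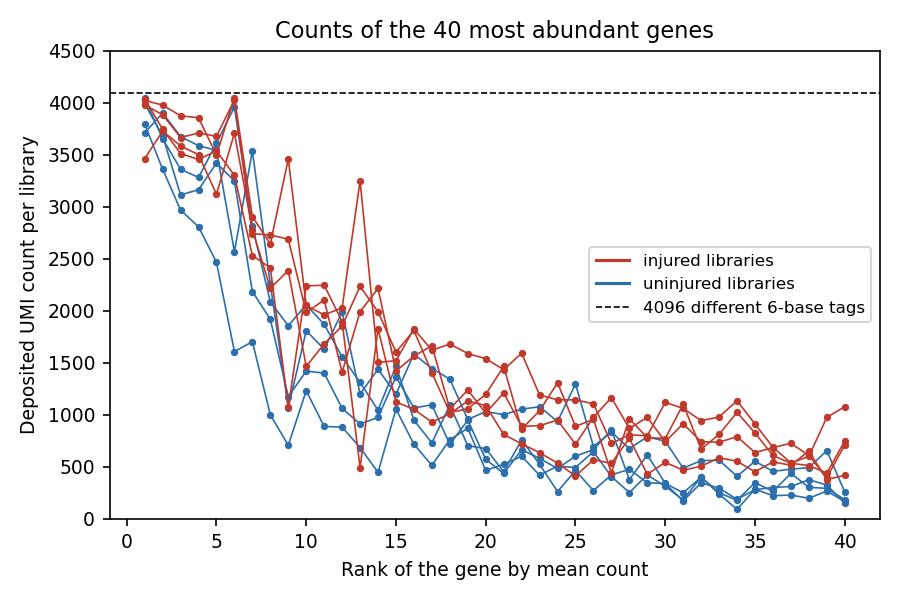
Deposited UMI count (linear axis) of the 40 genes with the highest mean count, 1 line per library coloured by group, with a dashed line at 4096, the number of different 6-base tags. The highest counts of the 8 libraries lie between 3727 and 4047, although library totals run from 112264 to 320199.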

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

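The tests of other splits without the block, of other pairings, of a batch behind the numbers, of library scaling and of the tag limit were chosen after their results were seen.

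In 2 of 16 sets of 4 values examined, 1 library lay far from the other three, where chance gives about 1 in 20. Uninjured library 1 had 9168 detected genes, against 7750 to 7983 in the other uninjured libraries. It was also the deepest of them, with 221177 UMIs against 112264 to 135994. At equal depth it had 7873 detected genes, against 7558 to 7750. ENSRNOG00000010208 was at 212 CPM in uninjured library 4, against 61.8 to 71.6 CPM in the others.

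Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least the 76 genes of the injury split, so chance cannot be excluded by this count. The other one, with 83 genes, was numbers 1 and 2 against 3 and 4, and edgeR called 0 genes in each of the remaining 33 (22 to 342 at an unadjusted p under 0.05, against 441 for injury). With the block on the numbers, injury gave 348 genes. Among the 8 splits that part all 4 pairs, 1 reached that count, the real one, and edgeR called 0 genes in each of the others (32 to 307 at an unadjusted p under 0.05, against 741), but 8 splits are too few for a share under 0.05. Every other split, with or without the block, counts the injury difference as spread between libraries, which by itself lowers its calls. The gap to 0 therefore does not measure how strong the injury difference is.

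Same-numbered libraries deviated together, and numbers 1 and 2 differed from 3 and 4. Of the 24 ways to pair injured with uninjured libraries, only 1, the real numbers, reached their mean correlation (0.363, the highest other 0.290). This argues against a chance pairing. As a block for the injury test, the real numbers gave 348 genes and the other pairings up to 248, against 76 without a block. A block on other pairs could thus also raise the calls. Crowding of abundant genes is argued against as the whole difference between the classes of numbers, since 79 genes differed without genes above a mean count of 400. Depth is argued against as the whole difference too, since 56 genes differed at equal depth, as many as for injury (22 to 88 over the draws), but 10 of 11 draws and not all reached the bound set against depth, so a part played by depth stays open. A shared day or library batch behind the numbers may remain: 284 genes differed between the classes with group as a term. The labels name no batch, so this cannot be told apart from other differences that rats of the same number shared. Independent differences between rats would match by number only by chance. No biological explanation was tested, since the design names none for the numbers.

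More genes were higher than lower without the block, 70 against 6. At an unadjusted p under 0.05 the excess was smaller, with 261 genes higher and 180 lower, so its size depended on the threshold. Deeper injured libraries are argued against as far as thinning levels depth, because 91.1% of calls were higher at equal depth. Thinning does not undo a limit on the counts of abundant genes, so it cannot decide on depth acting through such a limit. After the correction for tag collisions, edgeR called 71 genes higher and 5 lower. That correction was incomplete, as described below, so this part stays open. Scaling stays open: at least 94.5% were higher under 3 other scalings, but all 3 moved the median log2 fold change of all genes upward (total counts from -0.03 to 0.12), so none could have lowered the share. With the block the share was 59.8%, or 83.7% under total counts. The lower genes went from 140 to 60 under total counts and to 33 with DESeq2, run without filterByExpr. An effect of injury itself, which the design names, also stays open and was not tested apart from scaling.

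The highest counts of all 8 libraries lay just under 4096, the number of 6-base tags, with 0 counts above it. The counts of the 5 most abundant genes rose with the TMM-scaled totals of the tested genes with a median slope of only 0.118 on log scales. The 253 genes at 100 to 400 counts had a median slope of 0.936. TMM sets these totals from the bulk of the genes, so the 0.936 was largely built in. A limit set by 6-base tags would give a low slope for the most abundant genes. In deeper injured libraries such a limit would lower the abundant genes. Correcting for tag collisions moved the median log2 fold change of the 13 genes with a count above 2048 from -0.69 to -0.44 with the block, between the bounds set for the test, and 7 of the 9 called lower were still called lower, while 1 of the 13 was then called higher. Whether the limit explains the rest or these transcripts fell cannot be told apart, because the slope of the 5 genes was still 0.417 after the correction.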

How the results depend on the processing

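Against 70 higher and 6 lower genes, the calls moved by over 1.5 times with the replicate block (208 and 140), without a filter on low counts (225 and 13), with total counts as the only scaling (110 and 2), at adjusted p below 0.10 (113 and 30) or 0.01 (31 and 0 by edgeR, with 180 lower genes at an unadjusted p under 0.05) and, added after seeing the data, with the classes of numbers as a term (139 and 56). Lower genes alone moved with DESeq2 (19), run without filterByExpr, and with a mean count of at least 20 (10). All 70 higher genes remained among the calls without the filter, with the block and with total counts, 63 with DESeq2, 56 at a mean count of at least 20 and 48 with limma-voom. Of the 6 lower genes, 6 remained with the block, 3 without the filter, 2 with total counts and 5 with DESeq2. Total counts moved the median log2 fold change of all genes from -0.03 to 0.12. Leaving out 1 library gave 38 to 115 higher and 0 to 15 lower genes. The higher count moved without uninjured 1 (38), uninjured 2 (46), injured 1 (42) and injured 4 (115). The lower count moved without each: 10, 1, 1 and 15 without uninjured 1 to 4, and 0, 1, 1 and 13 without injured 1 to 4 (edgeR, 139 at an unadjusted p under 0.05 for the 0). The 2 printed risen genes kept their calls in all 21 (ENSRNOG00000010208) and 20 (ENSRNOG00000013057, not tested after thinning) alternatives. ENSRNOG00000024506 lost its call in 7 of 21, 6 leaving out a library and 1 thinning (edgeR adjusted p up to 0.132), and ENSRNOG00000025235 in 3 of 21 (up to 0.0651), with 0 reversed. The block changed no call of these 4 genes. Against the blocked 208 and 140, all alternatives were added after seeing the data: the counts moved with DESeq2 (80 and 33) and at equal depth (127 and 86), the lower count also with total counts (60) and without a filter (42). Leaving out 1 pair gave 95 to 318 higher and 47 to 202 lower genes, and the higher count moved without pair 1 (95) and 4 (318), the lower without pair 1 (47), 2 (91) and 3 (63). The cause was not tested for these changes. At equal depth injured libraries had 386 more detected genes, against 1424 at full depth. Equal depth did not level the share of the most abundant genes. Not run were the gene list tests and the removal of mitochondrially encoded genes, since no identifier could be named. Depth limits what was tested, 3073 of 12612 detected genes.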

Other observations

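The counts below were chosen after seeing the data. At an equal depth of 112264 UMIs per library, 28 genes were detected in all 4 injured libraries and in no uninjured library, and 6 in all 4 uninjured libraries and in no injured library (medians of 11 draws). Among the other splits of the 8 libraries into 4 and 4, the highest count in one direction was 22 and the median of the larger direction was 13. A count of 0 in a thinned library still allows an expected count of up to 3 in 112264 UMIs, at 95% confidence. The 10 most abundant genes took 12.5% of the counts in injured and 18.9% in uninjured libraries. On average, thinning thus left fewer UMIs for other genes in uninjured libraries, which favours detection in injured ones.

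Of the 83 genes that differed between the classes of numbers, 67 were higher and 16 lower in numbers 3 and 4. Without the block, 0 of them were among the 76 genes of the injury comparison, where independent lists of these lengths would share 2.05. Each of these fits counts the other difference as spread between libraries, which by itself lowers the overlap. Nothing is therefore concluded from the 0. With group as a term and the block on the numbers, 45 genes were called in both comparisons, where independent lists would share 32.2. That value takes every tested gene as equally likely to be called. The injury calls with the block had median mean counts of 38.6 (higher) and 78 (lower), against 22.8 for all tested genes. More abundant genes are easier to call in both comparisons, so nothing is concluded from the excess either.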
